A study of Homo sapiens with 49 samples.

How the data were processed

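Gene counts of bulk RNA sequencing libraries were studied from K562 cells, an established chronic myeloid leukaemia line, that carried dCas9-KRAB, a nuclease-dead Cas9 fused to a repressor domain. Cells received 1 guide RNA by lentivirus and were selected with an antibiotic. Guides were directed at ARL15-enh, an enhancer of the ARL15 gene, or at MYB-enh-3, the third of the enhancers of the MYB gene, with 10 guides for each region, and 2 non-targeting guides, sgNC-1 and sgNC-3, served as the control. Libraries were strand-specific and made from polyA RNA. Each set, of enhancer guides and its own non-targeting libraries, was a table of 56833 features.

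The values deposited by the authors were raw counts of reads per gene in each library, with no normalization. The submitters' processing notes named bcl2fastq 2.17.1.14, STAR 2.4.2a, Picard 1.117 and featureCounts 1.5.0, with the human genome build hg38. The strand setting of the counting, the treatment of reads that map to several places and the release of the gene annotation were not given in the sources used here. Genes were named by the symbols of the tables, and positions were those in the tables.

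The labels described 49 libraries, of which 47 were used. In the ARL15 set 1 library code headed 2 columns and another code headed none, so neither of these 2 columns was used. ARL15-enh sgRNA-2 and sgRNA-4 were therefore represented by 1 library each. The MYB set had 24 libraries, 2 for each guide. The ARL15 set had 23, with 18 from enhancer guides, 3 from sgNC-1 and 2 from sgNC-3. Total gene counts ran from 2860225 to 18000251 per library in the MYB set and from 8699738 to 23650310 in the ARL15 set. Libraries of the same guide were checked for copies: the chi-square per gene over genes with at least 20 counts was 2.76 to 14.2 in the MYB set and 5.57 to 59.1 in the ARL15 set, against 1 for reads drawn from the same library. A feature for the guide vector took 0.136 to 0.261% of the counts in the MYB set and 0.0960 to 0.469% in the ARL15 set, and was kept out of the totals and tests.

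The comparisons, the 23 gene lists, the rule for named genes and most alternative settings were fixed before the data were examined. Counts of the libraries of a guide were summed, so that the guide was the replicate, and the 10 guides of a region were compared with the 2 non-targeting guides of the same set. The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3, TMM normalization, filterByExpr), with a false discovery rate of 0.05. Values after ± are standard errors of the fitted log2 fold change. Each guide was also compared with all non-targeting libraries of its set, with libraries as samples and a shared estimate of the spread. The latter test rests on the spread between cultures, not between guides. The 2 non-targeting guides were compared with each other in the same way, and the difference between the effects of the 2 regions was tested as a contrast of the 4 groups. Genes within 1 Mb of MYB or ARL15 were also adjusted over that list alone.

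The gene lists covered erythroid maturation, globins, heme and iron, megakaryocyte, myeloid and lymphoid markers, haematopoietic transcription factors, reported targets of MYB, and partners of ARL15 in magnesium transport. Further lists held G1/S genes, G2/M genes, replication histones, ribosome biogenesis, p53 targets, cholesterol synthesis, hypoxia and glycolysis, immediate early genes, the integrated stress and unfolded protein responses, interferon-stimulated genes, targets of TGF-beta and BMP, heat shock proteins, transcripts encoded in mitochondria, and genes of HEK293T-like cells, the usual packaging line. They were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 3, at a preset correlation between genes of 0.01 and at an estimated correlation, and with fry. Relations between the level of the target gene and the mean of each list used 100000 permutations over the 10 guides of a region, two-sided, adjusted by Benjamini-Hochberg over the 23 lists.

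Named genes were MYB, HBS1L and ARL15 in both sets, the genes within 1 Mb that passed over that list alone, and up to 4 members of a list by smallest p. For each region the 12 largest rises and 12 largest falls were added, among genes that passed with a mean log2 CPM of at least 1 and with at least 8 of 10 guides on the same side of both non-targeting guides. The 5 largest differences between regions each way, and the 3 largest each way between the non-targeting guides, completed the rule.

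The tests were run on simulated counts, drawn from the mean and spread of each gene in these data. Changes were put only into genes above a minimum mean count. Genes were drawn independently, so differences that many genes share between libraries were absent, and recovery in the real counts may be lower. With guide sums, 64.2% of genes changed 1.5-fold, 91.0% of genes changed 2-fold and 98.5% of genes changed 4-fold were found in the MYB set. In the ARL15 set the recovered shares were 37.3%, 76.1% and 95.5%. For a single guide, sgRNA-1, they were 67.2%, 91.0% and 97.0% in the MYB set and 13.4%, 44.8% and 90.9% in the ARL15 set. False calls with guide sums were 10 of 179 calls in the MYB set and 7 of 146 in the ARL15 set. For the single guide they were 5 of 175 and 10 of 109.

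Alternatives were DESeq2's size factors in edgeR, DESeq2 1.42.0, limma voom with the guide as a random block, no filter on low counts, a mean of at least 1 CPM, libraries as samples with and without the replicate number as a block, thinning to a common depth, and leaving out each guide and each non-targeting library. In the ARL15 set the 4 highest library numbers, which belong to the 2 libraries of sgRNA-5 and to 2 of the 3 of sgNC-1, stood apart from the others, so values were also computed without these libraries, within them, and with a term for them. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the relations and plots.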

Results

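The series was a bulk follow-up of genes found when the same enhancers were repressed in single cells (Mosaic-seq). RNA was counted in 47 libraries of K562 cells with dCas9-KRAB: 24 in the MYB set, with a median total gene count of 15332578, and 23 in the ARL15 set, with a median of 13931586. The MYB set held 20 libraries of 10 MYB-enh-3 guides and 4 non-targeting libraries. The ARL15 set held 18 libraries of 10 ARL15-enh guides and 5 non-targeting libraries. The library with the lowest total, 2860225, was replicate 2 of MYB-enh-3 sgRNA-3. Unless stated otherwise, n was 10 enhancer guides against 2 non-targeting guides, intervals cover the spread between guides, and a gene counted as lower or higher with a guide where that guide lay beyond both non-targeting guides.

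The first comparison addressed which genes change when MYB-enh-3 is repressed. MYB, a transcription factor of blood progenitors (chromosome 6, 135181315 to 135219173, plus strand), fell by 2.01 ± 0.19 on the log2 scale, or 4.02-fold lower (adjusted p = 1.66e-06, lower with 10 of 10 guides). In the per-guide test MYB passed with 10 of 10 guides, and the remaining level ran from 19.3% of the non-targeting level with sgRNA-1 to 41.7% with sgRNA-3. Its neighbour HBS1L, which encodes a GTPase of ribosome rescue, was 1.39-fold lower (log2 -0.48 ± 0.07, adjusted p = 0.000115, 10 of 10 guides) and passed with each of the 10 guides. AHI1, a gene of the primary cilium on the other side of MYB, was 1.47-fold lower (log2 -0.55 ± 0.12, adjusted p = 0.00688, 10 of 10 guides). SGK1, a kinase gene 863 kb away, rose by 0.33 ± 0.07 (adjusted p = 0.00461, 10 of 10 guides).

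Of 7 tested genes within 1 Mb of MYB, 5 passed when adjusted over the list alone, and the same 5 passed over all genes. The remaining member of the 5 was RP1-32B1.3 (log2 -2.04 ± 0.22), whose exons overlap those of MYB on the opposite strand, so that its counts cannot be separated from MYB where the strand setting of the counting is unknown. ALDH8A1 (log2 -0.28 ± 0.77) and RP1-38C16.1 (log2 1.28 ± 0.69) did not pass. With sgNC-3 as the remaining control AHI1 no longer passed (log2 -0.45, adjusted p = 0.200), and with sgNC-1 as the remaining control SGK1 did not (log2 0.23, adjusted p = 0.271). ARL15, which lies on another chromosome, had a log2 change of -0.03 ± 0.09 (adjusted p = 0.891, 3 of 10 guides below both non-targeting guides).

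**Figure D1:**
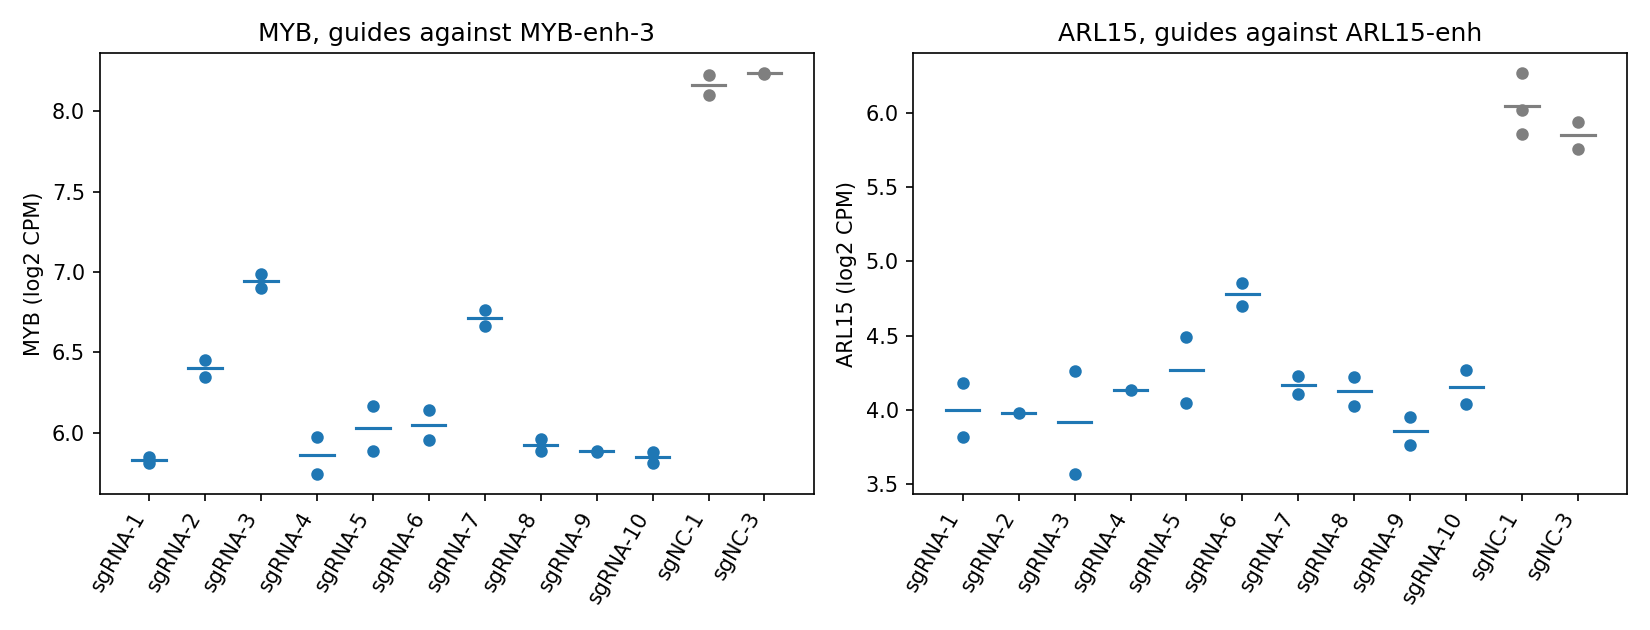
Level of MYB in the MYB set and of ARL15 in the ARL15 set (log2 CPM) for each guide. Points are libraries, lines are the means of each guide and grey marks non-targeting guides, and MYB with sgRNA-3 and ARL15 with sgRNA-6 kept the largest shares of the non-targeting level, 41.7% and 43.4%.

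**Figure D2:**
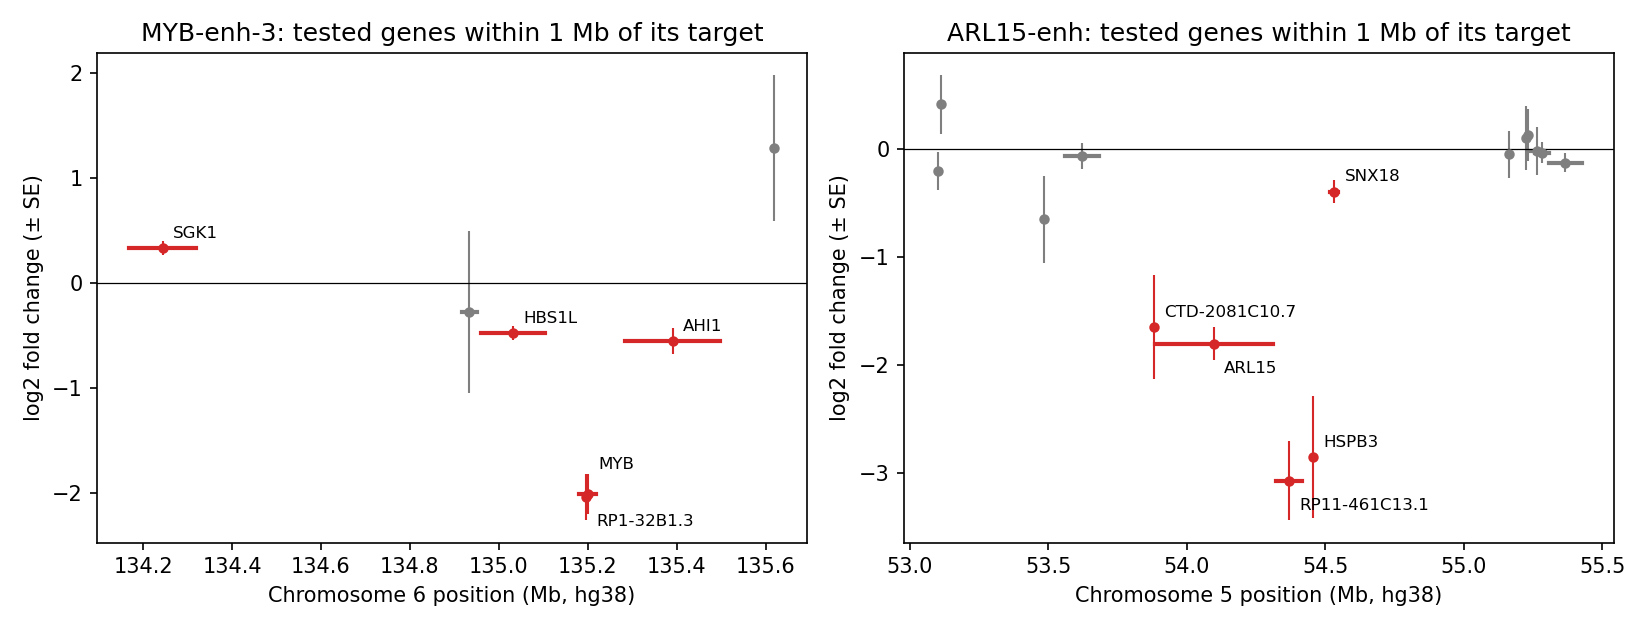
Log2 fold change of tested genes within 1 Mb of MYB (left) and ARL15 (right) against position in Mb (hg38), with vertical bars for standard errors over 10 guides against 2 and horizontal bars for the extent of the gene. The genes that passed over the list alone were 5 near MYB and 5 near ARL15.

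Across the genome 1714 of 20317 tested genes passed with MYB-enh-3 guides, 892 higher and the rest lower, and 267 of them changed more than 2-fold (153 higher and 114 lower). For 1597 of the 1714 genes all 10 guides lay beyond both non-targeting guides. The largest rises were in SLC30A10, a manganese exporter gene (6.74-fold, log2 2.75 ± 0.29), and TF, which encodes transferrin (6.28-fold, log2 2.65 ± 0.22). NFASC, a cell adhesion gene (log2 2.64 ± 0.35), and ALAS2, the erythroid form of the first enzyme of heme synthesis (5.07-fold, log2 2.34 ± 0.21), followed. SLC7A8, an amino acid transporter gene (log2 1.91 ± 0.17), ABCG2, a transporter gene whose protein exports porphyrins (log2 1.86 ± 0.24), CD93 (log2 1.86 ± 0.20) and RHCE, a blood group antigen gene (log2 1.84 ± 0.18), rose as well. CRYM (log2 1.87 ± 0.39), CCDC80 (log2 1.80 ± 0.30), TINAGL1 (log2 1.80 ± 0.28) and the pseudogene EIF5AP2 (log2 1.74 ± 0.33) completed the 12 largest rises within these limits. Adjusted p of these 12 genes was at most 0.004, with CRYM the highest, and each was higher with 10 of 10 guides.

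Within the same limits, the largest falls after MYB and RP1-32B1.3 were in PLAU, the gene of urokinase (3.74-fold lower, log2 -1.90 ± 0.23), and CD3D, a subunit of the T cell receptor complex (log2 -1.88 ± 0.25). KIT, the receptor of stem cell factor, was 2.99-fold lower (log2 -1.58 ± 0.21), and VIM, which encodes the filament protein vimentin, was 2.86-fold lower (log2 -1.52 ± 0.17). P2RX5, an ATP-gated channel gene (log2 -1.64 ± 0.16), and LPPR3 (log2 -1.62 ± 0.15) also fell. The other falls were in noncoding features, RP11-124N14.3 (log2 -1.56 ± 0.18), RP11-844P9.5 (log2 -1.53 ± 0.15), RP11-844P9.6 (log2 -1.50 ± 0.19) and RP11-874J12.1 (log2 -1.50 ± 0.17). RP11-124N14.3 overlaps exons of VIM on the opposite strand, the pair RP11-844P9.5 and RP11-844P9.6 share exons, and exons of TF, RHCE, ALAS2, P2RX5, PLAU, LPPR3 and TINAGL1 also overlap those of other features. Adjusted p of these falls was at most 4.71e-05, and each was lower with 10 of 10 guides.

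The count of 1714 depended on the controls and on depth: 632 genes passed without sgNC-1, 527 without sgNC-3, and 976 after all libraries were thinned to the depth of the smallest. Without the low-depth library 1681 genes passed, an alternative added after the data were seen. CRYM lost its call without sgNC-3 (adjusted p = 0.152), EIF5AP2 without sgNC-3 (adjusted p = 0.0525) and after thinning (adjusted p = 0.156), and TINAGL1 after thinning (adjusted p = 0.077).

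Genes of erythroid maturation rose together with MYB-enh-3 guides. Of 31 tested members 26 rose and none fell (28 rose when adjusted over the list alone), with GYPB (log2 1.58 ± 0.11), GYPE (log2 1.08 ± 0.10) and RHCE, genes of the red cell surface, among them. The list passed camera (adjusted p = 7.92e-28) and fry (adjusted p = 0.000295), with adjusted p = 0.144 with an estimated correlation. Of 9 tested globin genes 8 rose, the same count as over the list alone, among them HBE1 (log2 1.44 ± 0.13), HBG2 (log2 1.09 ± 0.12) and HBZ (log2 1.72 ± 0.20), the embryonic and fetal chains. The exception, HBQ1, had a log2 change of 0.02 ± 0.18. The globin list passed camera (adjusted p = 6.75e-12), with adjusted p = 0.144 with an estimated correlation. Of 21 heme and iron genes 12 rose and none fell (17 over the list alone), including FECH, the last enzyme of heme synthesis (log2 0.96 ± 0.10), PPOX (log2 0.88 ± 0.11) and the mitochondrial iron importer gene SLC25A37 (log2 1.22 ± 0.17). That list passed camera (adjusted p = 4.98e-12), with adjusted p = 0.144 with an estimated correlation. GYPB with GYPE, the 2 RH genes, HBA1 with HBA2 and HBG1 with HBG2 are close paralogs, and exons of HBE1 and HBG2 overlap, and reads shared among them were not excluded.

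Lists of the cell cycle and of chromatin also held more rises than falls. Of 21 tested replication histone genes 8 rose and none fell (12 over the list alone), such as HIST1H2AI (log2 0.74) and HIST1H2AG (log2 0.61). These transcripts mostly lack polyA tails. The list passed camera (adjusted p = 2.71e-05), with adjusted p = 0.269 with an estimated correlation. Of 45 G2/M genes 6 rose and none fell (7 over the list alone), including NUSAP1 (log2 0.44) and CCNA2, the gene of cyclin A2 (log2 0.28), with camera's adjusted p = 0.000178 and adjusted p = 0.269 with an estimated correlation. Of 42 G1/S genes 6 rose and 2 fell (10 and 2 over the list alone). RRM2, a subunit of ribonucleotide reductase, rose by 0.31 (log2), and CDCA7 fell by 0.27. For this list camera gave an adjusted p = 0.0217, with adjusted p = 0.325 with an estimated correlation. Genes of ribosome biogenesis went the other way: 5 of 38 fell and none rose (13 fell over the list alone), among them NOP16 (log2 -0.33), MYBBP1A (log2 -0.23) and NOP14 (log2 -0.22). Here camera gave an adjusted p = 2.56e-06, with adjusted p = 0.269 with an estimated correlation. The counts depended on the tool and on depth: falls of ribosome biogenesis genes were 11 with DESeq2, 14 with voom and 2 after thinning. Rises of G2/M genes were 7, 7 and 2, with 1 fall in DESeq2, and rises of G1/S genes 8, 10 and 3.

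Most lists of regulators and lineages held both rises and falls, and camera called none of these. Of 26 haematopoietic transcription factors 6 rose and 8 fell, MYB itself among the falls (9 and 9 over the list alone). Rises and falls of this list were 8 and 9 with voom, and 3 and 7 after thinning. TAL1 (log2 0.56) and KLF1 (log2 0.40), regulators of red cell genes, rose, and GATA2 (log2 -0.57), a factor of progenitors, and ETV6 (log2 -0.92) fell. Of 15 reported MYB targets 3 rose and 4 fell, with MYB itself, KIT and MYADM (log2 -1.11) among the falls, and without MYB the list mean was -0.10 in place of -0.23. Of 16 megakaryocyte genes 3 rose, including THBS1 (log2 0.75) and CD9 (log2 0.63), and 2 fell, F2RL3 (log2 -0.87) and GP6 (log2 -0.60). Of 15 myeloid genes 1 rose, CEBPE (log2 2.15), and 3 fell, including LGALS1, the gene of galectin-1 (log2 -0.91). CEBPE was not among the 12 largest rises because it did not meet their limits on mean level or on the side of the guides. Of 6 lymphoid genes CD3D alone passed, while 2 fell without the low-depth library and 2 of 4 fell with voom. Of 7 HEK293T-like genes 1 rose and 2 fell.

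Among stress and metabolic lists, 4 of 18 p53 targets rose and none fell, including BTG2 (log2 1.03) and GDF15 (log2 0.81), with camera's adjusted p = 0.0728 and fry's adjusted p = 0.00745. Of 25 cholesterol genes 4 rose, such as SQLE (log2 0.35), and 2 fell. Of 26 immediate early genes 2 rose and 6 fell, with falls in IER3 (log2 -0.87), FOSL1 (log2 -0.79) and EGR1 (log2 -0.53). Of 29 hypoxia and glycolysis genes 2 rose and 3 fell, and SLC2A1, a glucose transporter gene, rose by 0.82 (log2) while PKM fell by 0.59. Integrated stress and unfolded protein genes had 4 rises and 3 falls of 28, interferon-stimulated genes 2 rises and 1 fall of 25, and TGF-beta and BMP targets 1 rise and 3 falls of 16. Rises and falls of integrated stress genes were 3 and 7 with voom, and 3 and 0 after thinning. Those of immediate early genes were 2 and 7 with voom, and 2 and 3 after thinning. No member passed among 14 heat shock genes (camera's adjusted p = 0.0341, adjusted p = 0.555 with an estimated correlation), 13 mitochondrial transcripts or 16 genes of magnesium transport. In edgeR 3 members of each of these 3 lists had an unadjusted p under 0.05, and DESeq2 called 2 heat shock genes, 0 mitochondrial transcripts and 1 gene of magnesium transport. Interferon-stimulated genes passed fry (adjusted p = 0.0313) and not camera (adjusted p = 0.253). Adjusted over the list alone, rises and falls were 4 and 5 for MYB targets, 3 and 3 for megakaryocyte, 3 and 5 for myeloid and 0 and 2 for lymphoid genes. They were 5 and 2 for cholesterol, 2 and 7 for immediate early, 3 and 3 for hypoxia and 4 and 6 for integrated stress genes, and the counts of p53, interferon-stimulated, TGF-beta and BMP, HEK293T-like, heat shock, mitochondrial and magnesium lists were as over all genes. The median was above 0 and camera's direction was down for MYB targets (median log2 0.02, mean -0.23), integrated stress genes (median 0.002, mean 0.04) and TGF-beta and BMP targets (median 0.03, mean 0.003), and hypoxia genes had a median of -0.02 and a mean of 0.01. Under DESeq2, its size factors in edgeR, voom and thinning, the median kept its sign in each of the 7 lists described above for erythroid maturation, globins, heme and iron, the cell cycle, histones and ribosome biogenesis. The sign changed under at least 1 of them for the MYB target, magnesium, hypoxia, integrated stress and TGF-beta lists.

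**Figure D3:**
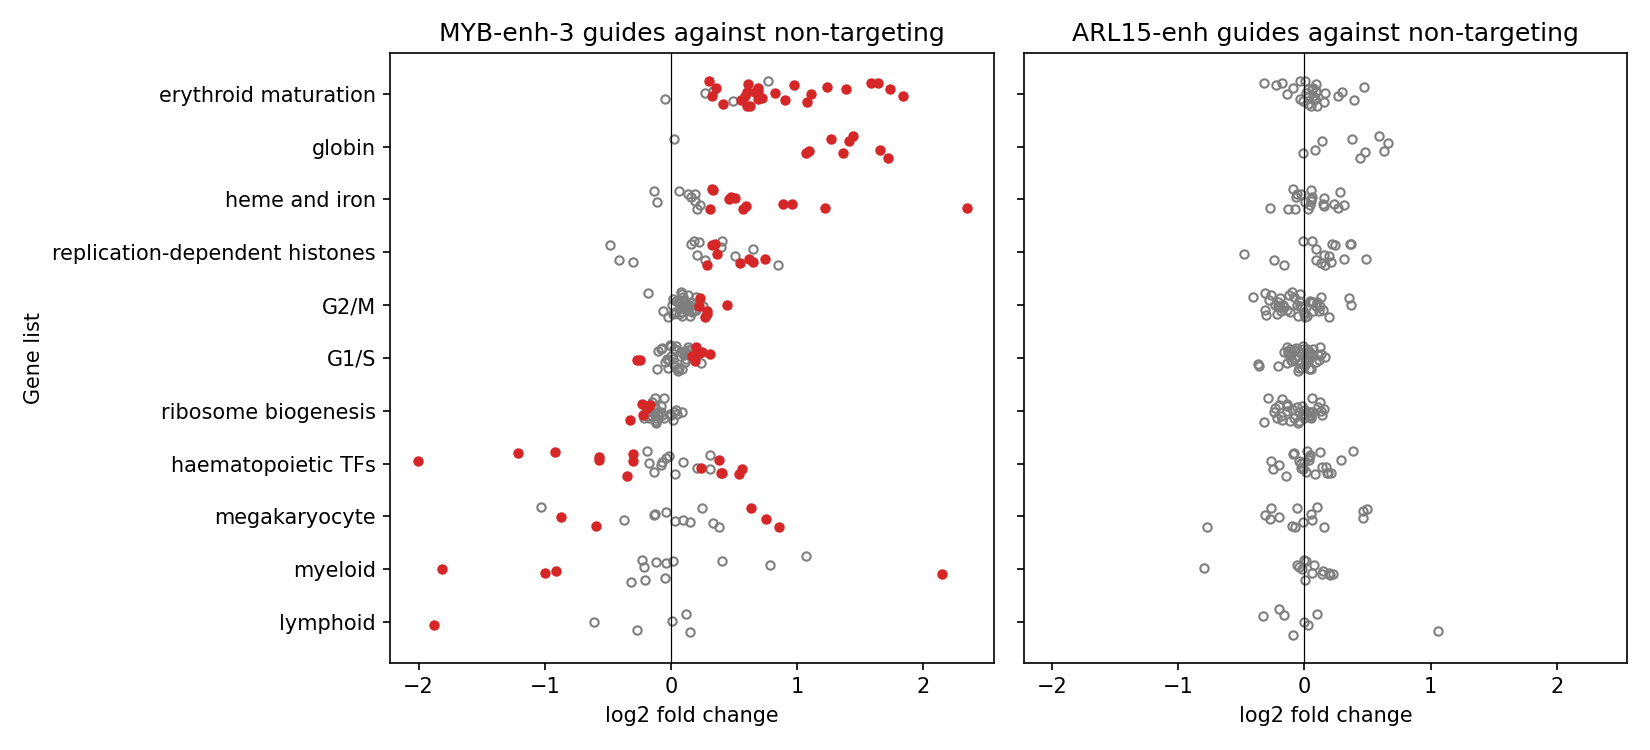
Log2 fold change with MYB-enh-3 guides (left) and ARL15-enh guides (right) of the tested members of 11 of the fixed lists, 1 point per gene (10 guides against 2). Filled points are genes that passed over all genes, and with MYB-enh-3 26 of 31 erythroid maturation genes, 8 of 9 globin genes and 12 of 21 heme and iron genes rose.

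Guides differed in how far they lowered MYB. Over the 10 guides the mean of the erythroid maturation list was higher where MYB was lower (Pearson r = -0.905, permutation p = 0.00141, adjusted over 23 lists 0.0324). Spearman rho was -0.709 (permutation p = 0.0267, adjusted 0.437), so the rank relation did not pass the correction. Without the 2 guides farthest from the median, sgRNA-3 and sgRNA-7, r was -0.848 (permutation p = 0.0276, adjusted 0.330), so the adjusted call rested on these guides. Without sgRNA-3 alone, 1 of whose libraries was the low-depth one, r was -0.832 (permutation p = 0.0131, adjusted 0.301). The heme and iron list (r = -0.839, rho = -0.624, permutation p = 0.00548 and 0.0610, adjusted 0.0630 and 0.437, r = -0.776 without the 2 guides) and the globin list (r = -0.764, rho = -0.576, permutation p = 0.00993 and 0.0891, adjusted 0.0761 and 0.437, r = -0.704 without the 2 guides) did not pass. The number of genes called per guide ran from 241 with sgRNA-3 to 1496 with sgRNA-4.

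**Figure D4:**
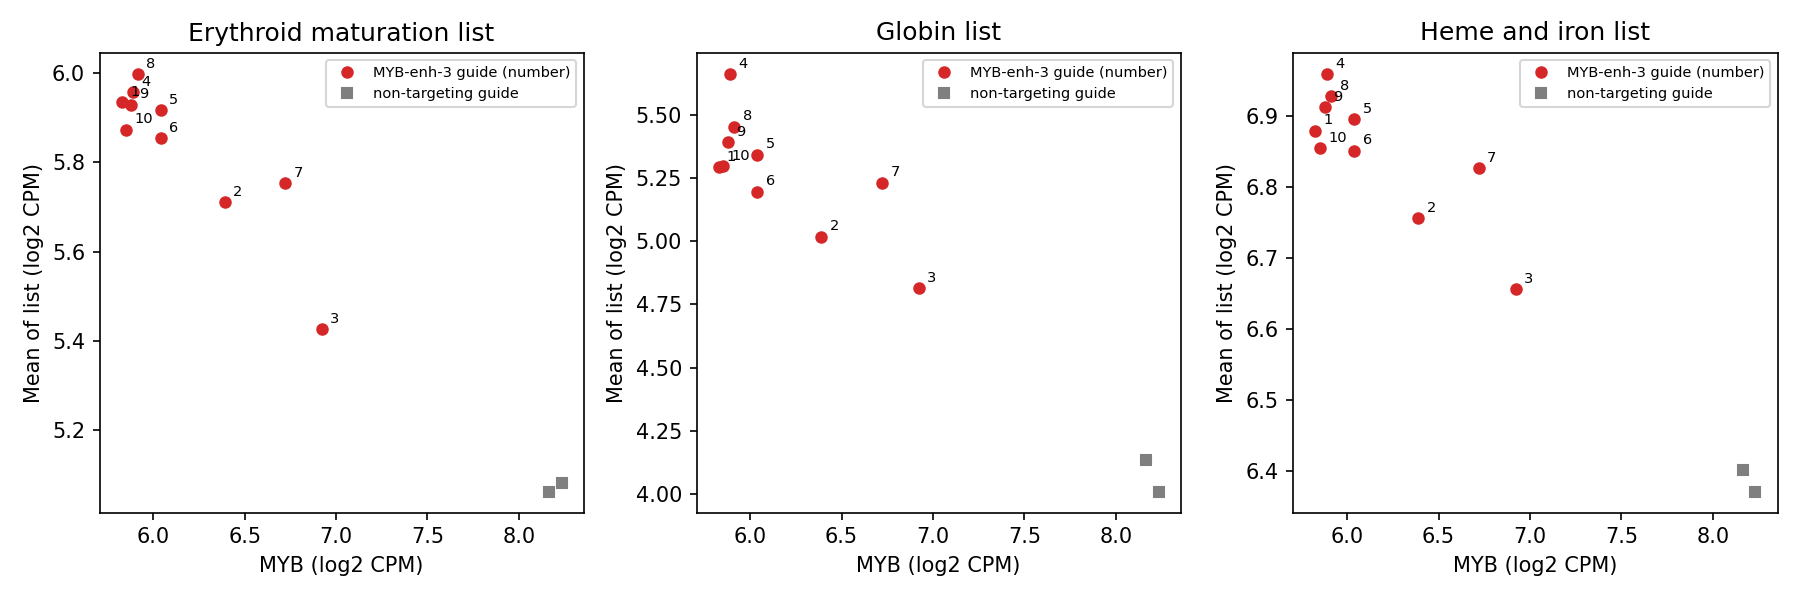
Mean log2 CPM of the erythroid maturation, globin and heme and iron lists against log2 CPM of MYB, 1 point per guide sum. Numbers are MYB-enh-3 guides and squares are non-targeting guides, and over the 10 guides Pearson r was -0.905, -0.764 and -0.839.

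The second comparison addressed which genes change when ARL15-enh is repressed. ARL15, a gene of a small GTPase-like protein (chromosome 5, 53883945 to 54310582, minus strand), was 3.49-fold lower (log2 -1.80 ± 0.15, adjusted p = 2.93e-05, lower with 10 of 10 guides). RP11-461C13.1, a noncoding gene that starts 10.4 kb from ARL15 on the opposite strand, was 8.43-fold lower (log2 -3.08 ± 0.37, adjusted p = 0.00233, 10 of 10 guides). These 2 were the genes that passed of 20912 tested, and 1040 genes had an unadjusted p under 0.05. MYB (log2 -0.03 ± 0.11, adjusted p = 0.999) and HBS1L (log2 -0.23 ± 0.13, adjusted p = 0.987) did not pass.

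Of 15 tested genes within 1 Mb of ARL15, 5 passed when adjusted over the list alone and 2 over all genes. The other members of the 5 were HSPB3, a small heat shock protein gene (log2 -2.85 ± 0.57, list adjusted p = 0.000564, adjusted p over all genes = 0.644), CTD-2081C10.7 (log2 -1.65 ± 0.48, list adjusted p = 0.00950), and SNX18, a sorting nexin gene (log2 -0.39 ± 0.11, list adjusted p = 0.00885), each lower with 10 of 10 guides. HSPB3 and CTD-2081C10.7 had few counts, 0 to 9 per enhancer library for both, against 8 to 34 and 9 to 30 per non-targeting library. The levels of NDUFS4 (log2 -0.06 ± 0.12) and DHX29 (log2 -0.03 ± 0.10), also in the window, did not pass.

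In the per-guide test in edgeR ARL15 passed with 9 of 10 guides, at 22.8% of the non-targeting level with sgRNA-9 up to 30.7% with sgRNA-5. With sgRNA-6 it was at 43.4% and did not pass in edgeR (log2 -1.21 ± 0.20, adjusted p = 0.106), while DESeq2 called ARL15 with all 10 guides (adjusted p = 3.99e-05 with sgRNA-6). The genes called were ARL15 and RP11-461C13.1 with 6 guides, ARL15 alone with sgRNA-2 and sgRNA-4, each of which had 1 library, and none with sgRNA-6 (edgeR, with 737 genes at an unadjusted p under 0.05 and ARL15 alone called by DESeq2). With sgRNA-9, 27 genes passed, 6 higher and 21 lower. DESeq2 called 84 genes with sgRNA-9, 58 with sgRNA-5 and at most 2 with each other guide. Among them ARHGDIB was 9.46-fold lower (log2 -3.24 ± 0.21), a gene chosen after its values were seen.

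No member of the fixed lists passed with ARL15-enh guides other than ARL15 itself, in the list of magnesium transport. Adjusted over the list alone, 1 haematopoietic transcription factor also passed, GFI1B, a repressor in erythroid cells (log2 0.38 ± 0.10, adjusted p over all genes = 0.987, 10 of 10 guides). The globin list was called by camera (adjusted p = 0.0457, adjusted p = 0.919 with an estimated correlation), with 0 of 9 genes passing in edgeR (1 at an unadjusted p under 0.05, 0 called by DESeq2), HBE1 at log2 0.63 ± 0.32, and fry's adjusted p at 0.928. For the other 22 lists camera's adjusted p was at least 0.350. Relations of the lists with the level of ARL15 over the 10 guides did not pass (smallest adjusted permutation p 0.862 of 23 lists, and 0.661 without sgRNA-5). Without the 2 guides farthest from the median, sgRNA-6 and sgRNA-9, the cholesterol (r = 0.856), G2/M (r = 0.943) and hypoxia (r = 0.885) lists reached an adjusted permutation p of 0.0389. The high-numbered libraries described below include those of sgRNA-5, the guide with the highest ARL15 among the 8 left. In them 13 of 25 cholesterol, 31 of 45 G2/M and 19 of 29 hypoxia genes were higher (camera's adjusted p = 0.00102, 5.1e-06 and 0.00102, with 0.527, 0.491 and 0.491 with an estimated correlation). Without sgRNA-5 alone r was -0.0145, 0.191 and -0.0603, and without all 3 guides it was 0.809, 0.857 and 0.731 with no list passing (smallest adjusted permutation p 0.207).

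The 4 high-numbered libraries of the ARL15 set differed from the other 19, in a fit with a term for enhancer guides, in 8252 of 18406 genes, 4085 higher and 4167 lower. Among them heat shock genes were higher (11 of 14, median log2 0.51, adjusted p = 0.00102, adjusted p = 0.527 with an estimated correlation) and genes of the integrated stress and unfolded protein responses lower (18 of 29, with 7 higher, median log2 -0.61, adjusted p = 0.0118, adjusted p = 0.527 with an estimated correlation). These libraries were sgRNA-5 and 2 of the 3 of sgNC-1, so both arms were present within them. ARL15 had a log2 change of -1.78 ± 0.14 without them (guide sums, adjusted p = 3.8e-07). Within them it was -1.80 ± 0.21 (2 libraries of sgRNA-5 against 2 of sgNC-1, adjusted p = 0.0113). With a term for them it was -1.77 ± 0.13 (18 libraries against 5, adjusted p = 1.8e-10). The last 2 fits, and that of the 4 libraries against the other 19, took libraries as samples. Libraries of the same guide counted as independent there, so these p-values are not comparable with those of guide sums. The genes called were 3, 2 and 2, and RP11-364B14.2 (log2 0.83) was the gene added without these libraries. The call of RP11-461C13.1 ended without sgNC-3 (log2 -2.87), where sgNC-1 alone was left as the control. Without sgRNA-5, 47 genes passed. That fit kept the 2 high-numbered libraries of sgNC-1 in the control and none in the enhancer arm. Its calls therefore cannot be told apart from the difference of these libraries.

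The third comparison set the effects of the 2 regions against each other. The difference passed for 294 of 21838 genes, 145 higher and 149 lower with MYB-enh-3 relative to ARL15-enh, and 276 of them were among the 1713 tested genes called with MYB-enh-3 guides. The effect on MYB differed by a log2 of -2.002 ± 0.28 (adjusted p = 0.000115) and the effect on ARL15 by 1.74 ± 0.20 (adjusted p = 1e-05). ALAS2 (2.38 ± 0.24) and TF (2.62 ± 0.59) were among the genes with higher effects of MYB-enh-3, and RP11-874J12.1 (-1.88) and P2RX5 (-1.83) among those with lower ones. The effect on HBS1L did not differ past the threshold (-0.27 ± 0.15, adjusted p = 0.559). The ARL15-enh effect on HBS1L that entered this contrast was -0.233, and without the high-numbered libraries of the ARL15 set it was 0.027. The contrast was not run without these libraries, so it cannot settle whether the fall of HBS1L was particular to MYB-enh-3. The other genes of the contrast carry the same limit, among them TF, which was lower in these libraries (log2 -2.83 ± 0.38). No gene was called in both regions in the same direction by edgeR, with 0.0834 expected among the lower genes and 1 shared by DESeq2. The count of 294 fell to 98 and 81 without sgNC-1 or sgNC-3 of the MYB set and to 176 without sgNC-3 of the ARL15 set, and was 558 with DESeq2 and 650 with libraries as samples.

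The background between controls was measured by comparing sgNC-1 with sgNC-3. In the MYB set 1 of 18989 genes passed, RNU6-1, a U6 small nuclear RNA gene on chromosome 15 (log2 3.34 ± 0.29, adjusted p = 3.92e-06), and 642 genes had an unadjusted p under 0.05. In the ARL15 set no gene passed of 20394 in edgeR, with 3311 at an unadjusted p under 0.05, 358 called by DESeq2 and RNU6-1 at log2 2.22 ± 0.34 (adjusted p = 0.0527). That count of 0 depended on single libraries, with 2761 genes without replicate 1 of sgNC-1, the library outside these 4, and 1586 without replicate 1 of sgNC-3.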

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

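The comparisons of each guide with the other 9 of its region, the test of ARHGDIB against ARL15 and all tests of RNU6-1 were chosen only after the result was seen.

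With MYB-enh-3, sgRNA-3 stood apart from the other 9 guides in 8 of the named genes. It had the lowest log2 CPM of ABCG2 (1.956), ALAS2 (5.848), NFASC (1.216), RHCE (4.863) and TINAGL1 (0.910), and the highest of CD3D (2.556), RP11-124N14.3 (6.603) and VIM (8.196), so each lay nearer to the non-targeting level. CCDC80 was lowest with sgRNA-7 (1.219). In these data 13 of 47 groups had such a lone value, where chance gives about 1 in 20, and the genes are not independent because they share guides.

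The erythroid maturation list, which graded over the guides with MYB, also followed the total count (r = 0.753, permutation p = 0.0404), and r was 0.0968 without sgRNA-3, which holds the low-depth library. Uneven depth is argued against as the whole cause, since r with MYB was -0.832 without that guide against -0.905 with all 10, although the call after adjustment was lost (adjusted permutation p = 0.301). The amount of guide vector showed r = 0.236 and rho = 0.297 with the list (permutation p = 0.431 and 0.408), and without sgRNA-3 that r was 0.767 (permutation p = 0.0127), so a dose of the vector stays open. A candidate explanation is that the level of MYB left by each guide sets the erythroid genes, a hypothesis found and tested on the same guides. Other effects of the guides that move with MYB, such as the strength of repression of HBS1L (r = 0.581 and rho = 0.624 with MYB, permutation p = 0.0790 and 0.0603), stay open.

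With ARL15-enh, sgRNA-9 had 27 genes called in edgeR and the other guides at most 2, and in DESeq2 84, against 58 with sgRNA-5 and at most 2 with the rest. Among them was ARHGDIB, with log2 CPM of 2.81 and 3.19 in its 2 libraries and 5.69 to 6.58 in the other 21. The fall did not rest on a single library, with a gap of 2.504 between the higher of the 2 and the lowest other library. The gene was chosen after its values were seen, and a fall of this size over 2 libraries requires both to be low, so the gap is no independent test. The loss of ARL15 is argued against by the median log2 change of ARHGDIB with the other 9 guides, -0.015. Repression that spread from a site near ARHGDIB stays open: 6 of 9 tested genes within 1 Mb had a lower level with sgRNA-9 than with the other guides, 1 of them, ATF7IP, at an unadjusted p under 0.05 (log2 -0.458 ± 0.165), and 0 passed (smallest list adjusted p = 0.105, edgeR). The tested genes nearest to ARHGDIB were C12orf60, higher with sgRNA-9 (log2 0.409 ± 0.253), and WBP11 (log2 -0.092 ± 0.142), while ATF7IP lies farther away. Binding of this guide at a site confined to ARHGDIB could also explain the fall, and was not tested because no genome sequence was searched for matches.

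In comparisons of each guide with the other 9 of its region, the most genes, 1967, passed with ARL15-enh sgRNA-5, whose libraries are high-numbered, and 123 passed with MYB-enh-3 sgRNA-3, which holds the low-depth library. With ARL15-enh sgRNA-9 28 genes passed, and CHST2 (log2 -2.10), ZNF280A (log2 -1.79), PPP6R2 (log2 -1.48), CORO1A (log2 -1.51) and DLC1 (log2 -1.36) were lower. With MYB-enh-3, 14 genes passed with sgRNA-4 and 11 with sgRNA-10, and with sgRNA-10 EGLN3 (log2 -1.94), ZNF675 (log2 -1.89), ZNF726 (log2 -1.47) and STAC3 (log2 -1.31) were lower.

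ARL15 was highest with sgRNA-6 among the ARL15-enh guides (4.801 log2 CPM, next 4.316). HBS1L was highest with sgRNA-5 (8.388, next 8.067), whose libraries are high-numbered. Among the 4 non-targeting libraries of the MYB set, MYB was lowest in replicate 1 of sgNC-1 (8.102, next 8.226).

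The share of the guide vector was above the highest non-targeting library in 14 of 20 enhancer libraries of the MYB set, up to 0.261%. In the ARL15 set this held for 9 of 18 enhancer libraries, up to 0.469%.

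The effects of the regions differed by a test of the difference itself for 294 genes. The difference in log2 effect, MYB-enh-3 minus ARL15-enh, was -2.087 for RP1-32B1.3, -2.002 for MYB, -1.997 for CD3D, -1.88 for RP11-874J12.1 and -1.833 for P2RX5. It was 3.005 for RP11-461C13.1, 2.617 for TF, 2.396 for SLC30A10, 2.376 for ALAS2 and 2.363 for NFASC. The sets were prepared with separate non-targeting libraries, and the contrast used those of each set. High-numbered libraries of the ARL15 set entered it, and it was not run without them.

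For the 1714 genes of MYB-enh-3, of the 66 ways to choose 2 of the 12 guides as the control, only the real one gave as many. The highest other gave 1. This argues against chance, although 1 of 66 is the smallest share the test can give. Every other split also places at least 1 non-targeting guide among the enhancer guides, which widens the spread and lowers the count. Handling shared by the non-targeting libraries is not addressed by this test. For the 2 genes of ARL15-enh, 3 of 66 splits gave as many, a share under 0.05, yet the highest other split gave 6069. That split set sgRNA-5 and sgNC-1 apart, which hold the 4 high-numbered libraries, and points to a structure of the samples; within those libraries ARL15 and RP11-461C13.1 were the 2 genes called. The third such split set sgRNA-6 and sgRNA-9 apart, with 2 genes.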

How the results depend on the processing

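The settings without the low-depth library, with a term for the 4 high-numbered libraries, within these libraries, and per guide without them, and the relations without sgRNA-3, without sgRNA-5 or without sgRNA-5 and the 2 farthest guides, were tests chosen only after the data were seen. MYB with MYB-enh-3 and ARL15 with ARL15-enh kept their direction and their call under every setting run, 25 and 28 settings. Of values that answer a comparison, 202 stayed and 27 moved. A count stayed if its ratio to the main count was within a fixed limit, so that 2156 against 1714 genes stayed and 976 moved. A fold change stayed if it kept its sign and its call. Of the other values, 1121 stayed, 12 moved, 4 changed sign, 6 gained a call and 20 lost one. The cause was not tested except where stated.

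Genes called with MYB-enh-3 ran from 527 (without sgNC-3) over 632 (without sgNC-1) to 2065 (without sgRNA-3) in leave-one-out fits, and were 976 after thinning. Of these, 511, 618, 1702 and 892 were among the 1714. They were 2156 with DESeq2 (1659 shared) and 2216 with limma voom (1615 shared). The median log2 change of all genes was 0.16 with DESeq2 and with no filter, where genes with few counts were included, against 0.01. The median number of genes per guide was 626 with sgNC-1 and 702 with sgNC-3 as the only control. Genes between the non-targeting guides of the MYB set were 102 with no filter.

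Genes called with ARL15-enh were 6 with DESeq2 and ran from 1 (without sgNC-3) to 47 (without sgRNA-5) in leave-one-out fits. Without sgNC-1 they were 3, with GAR1 (log2 -1.07) added. Genes passing near ARL15 were 8 with no filter, 3 with a mean of at least 1 CPM and 3 without sgNC-1. HSPB3 ran from -3.312 (without sgNC-1) to -2.23 (without sgNC-3) and gained the call over all genes without sgRNA-5 (adjusted p = 0.0436). In that fit, which also gave the 47 genes, only the control held high-numbered libraries, so its calls cannot be told apart from their difference. The median number of genes per guide was 51 with no filter. Between the non-targeting guides of the ARL15 set the count was 1 with DESeq2's size factors, 1004 with no filter, 358 with DESeq2, and 0 to 2761 in leave-one-out fits (1 without replicate 2 of sgNC-1, 1586 without replicate 1 of sgNC-3).

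The difference between regions gave 650 genes with libraries as samples, 558 with DESeq2, and 81 to 206 in leave-one-out fits (81 without sgNC-3 and 98 without sgNC-1 of the MYB set, 176 without sgNC-3 and 206 without sgNC-1 of the ARL15 set). The overlap of calls was 1 with DESeq2.

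Among the log2 changes of single genes, sign changes were limited to values that never passed: ARL15 with MYB-enh-3 (0.026 without sgNC-1, down to -0.104 without sgNC-3), HBS1L with ARL15-enh (0.002 without sgNC-1, -0.438 without sgNC-3 and 0.027 without the 4 high-numbered libraries) and MYB with ARL15-enh (0.019 without sgNC-3, down to -0.073 without sgNC-1).

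The replicate numbers showed no pairing of the libraries across all guides. Over pairs of guides the differences between replicates 1 and 2 correlated at -0.346 to 0.412 (MYB set, median -0.0132) and -0.453 to 0.496 (ARL15 set, median 0.0437). On average 6 of 12 guides in the MYB set and 7 of 10 in the ARL15 set correlated positively with the others. A replicate effect shared by part of the guides was therefore not excluded, and high-numbered libraries entered the check of the ARL15 set. With the replicate number as a block, MYB-enh-3 gave 2402 genes against 2452 without, ARL15-enh 2, the difference 534 and the non-targeting guides of the ARL15 set 1. Thinning, which lowers depth, left the 2 genes of ARL15-enh.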

Other observations

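The tests of families of gene symbols and all tests of RNU6-1 were chosen only after the result was seen.

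Among genes that rose with MYB-enh-3 guides, 3 families of gene symbols were more frequent than among all tested genes. Tetraspanins, membrane organisers, held 7 rises of 15 tested (0.659 expected, Fisher's exact test, adjusted p = 9.5e-05), such as TSPAN32 (log2 1.09), TSPAN5 (log2 0.66), TSPAN14 (log2 0.53) and TSPAN13 (log2 0.45). Solute carriers held 28 rises of 237 (10.4 expected, adjusted p = 0.000103), and histone genes, which include those of the fixed list, 14 of 57 (2.5 expected, adjusted p = 1.03e-05). Families, chromosomes and gene types gave 262 tests, of which 5 passed, and the remaining 2 were protein-coding genes in both directions. Protein-coding genes held 749 rises of 12649 tested (555 expected). Gene types came from a reference annotation, GENCODE, matched by symbol, which named 29681 of the 56833 features. Protein-coding genes under a symbol absent from it were not counted as such. Expected counts of the families were over all tested genes, noncoding ones included, so they are low for families of protein-coding genes. The families were not tested among protein-coding genes alone.

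The 4 high-numbered libraries of the ARL15 set differed from the other libraries in single genes as well. S100P (log2 -4.85 ± 0.72), INHBE (log2 -3.40 ± 0.49), TF (log2 -2.83 ± 0.38) and CHAC1 (log2 -2.74 ± 0.37), a target of the integrated stress response, were lower. CD44, an adhesion receptor gene, (log2 1.99 ± 0.11) and HBM (log2 1.88 ± 0.20) were higher, while the 9 globin genes as a list held 4 higher and 4 lower (median log2 -0.49). Of 45 G2/M genes 31 were higher and 3 lower (adjusted p = 5.1e-06, adjusted p = 0.491 with an estimated correlation), and of 13 mitochondrial transcripts 11 were higher (adjusted p = 0.0022, adjusted p = 0.527 with an estimated correlation).

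RNU6-1 differed between guides, from 0.540 CPM with sgNC-3 in the MYB set to 67.8 with ARL15-enh sgRNA-9. The amount of vector is argued against as the whole cause (Spearman rho 0.221 with the vector share over 24 guides, permutation p = 0.302, bootstrap interval -0.222 to 0.590, with a range of 2.72-fold in the vector share against 126-fold in RNU6-1), as is a change of U6 genes in general, since 1275 other U6 loci had a log2 ratio of 0.05 between the 4 highest guides and the rest. The share of the variance that lay between guides was 0.976 over 47 libraries of 22 guides, and sgNC-1 was above sgNC-3 in both sets (5.44 against 0.540 and 4.84 against 1.15 CPM). A candidate explanation is that reads from the U6 promoter cassette of the vector run into the guide and align to RNU6-1 when the first bases of the guide match it, which the guide sequences, not given in the sources used here, would test. No other biological explanation was tested.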
